A study of Drosophila melanogaster with 12 samples.

How the data were processed

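The study profiled RNA from the fat body, the larval organ that stores fat and glycogen, of female Drosophila melanogaster collected as wandering larvae at the end of larval growth. Per the labels, males of VDRC stock 60000 (control) or of VDRC stock 37058, which carries UAS-EcR RNAi, were crossed to females with UAS-Dcr2 and the driver r4-GAL4. Larvae were reared on semi-defined food with 0.15 M sucrose or 0.5 M sucrose. The labels' protocols state that fat bodies were dissected, sheared and separated by centrifugation, that ribosomal RNA was removed with RiboZero, and that bar-coded cDNA was read on an Illumina HiSeq instrument. The 12 libraries fall into 4 groups of 3.

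The authors deposited 1 table with a normalised signal per gene and library for 10047 genes. The submitters' processing notes name TopHat 1.3.2, Bowtie 0.12.7, Cufflinks 1.1.0 and edgeR, without their roles. The genome build, the annotation, the strand setting and the filter on genes were not given in the sources used here. The values were not whole, none was 0, the lowest was 0.0933, and the medians per library lay between 103 and 111. They behaved as read counts adjusted by quantiles to a common library size. Inverting such an adjustment, with 1 scale per library and each gene's group mean as its expected value, turned 96.9% to 100% of the values between 5 and 40 into whole reads within a tolerance of 0.05. The reads recovered in this way summed to between 8520039 and 11598357 per library. The sums of the signal itself ran from 8864826 to 15045575. How the values were made is inferred here from the values alone, and such an adjustment can change the spread between libraries relative to that of raw reads.

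The design fixed before the data were examined foresaw a count model if the table held counts. The table held a normalised signal, so the path written for normalised values was used. Values were transformed as log2(value + 1). Genes were to have a mean of at least 1 over the 12 libraries, and all 10047 did, the lowest mean being 1.67. Fold changes are on this log2(value + 1) scale, which understates changes of low genes, and 928 genes had a mean under 10. limma 3.58.1 in R 4.3.3 fitted 1 model of 4 groups to all 12 libraries, with a trended and robust empirical Bayes step. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The 5 contrasts were the EcR RNAi label against control on each diet, 0.5 M against 0.15 M sucrose in each genotype, and the interaction, which is the diet change in the libraries labelled EcR RNAi minus that in controls.

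Gene lists were fixed at the same time, 19 of pathways and 10 of cell types or sex. The pathway lists were ecdysone response, larval serum proteins, autophagy, lysosome, lipogenesis, lipolysis and fatty acid oxidation, glycolysis, pentose phosphate and polyol, glycogen and trehalose, sugar sensing, insulin and TOR signalling, immune effectors, detoxification, cytoplasmic ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, TCA cycle, chaperones and cell cycle. The others were salivary gland, hemocyte, muscle, midgut, cuticle and trachea, nervous system, gonad and germline, ring gland, Malpighian tubule and sex markers. Each list was set against the other genes with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists, and again with the correlation estimated from the data. At the estimated correlation camera called 0 of the 29 lists in each of the 5 comparisons.

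Named genes followed a rule fixed with the design. It took the 8 called genes with the largest rise and the 8 with the largest fall whose groups did not overlap and whose higher mean was at least 10. For the interaction it took 5 in each direction, without the demand on overlap. It added up to 3 members with the smallest p of each list described, and EcR, w and Dcr-2 as checks of the labels. Further members of a list are named below from the called members of that list, after their values were seen. Symbols are those of the table, and 9605 of its gene identifiers matched a current FlyBase name, which differed from the table's symbol for 2098 genes, while 442 did not match. In 4 cases a spreadsheet had turned the symbol into a date, and the current name was used. No coordinates are given, since the build is not given in the sources used here. Genes with near-identical copies, such as AttA and AttB, and overlapping genes can share reads, so their values are uncertain.

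The fit was tested on simulated counts for the 10047 genes, with 200 genes changed. For the contrast on 0.15 M sucrose it recovered 22.4% of changes of 1.5-fold, 71.6% of changes of 2-fold and 89.4% of changes of 4-fold, and 5.43% of its calls were false. For the contrast on 0.5 M sucrose these shares were 23.9%, 65.7% and 92.4%, with 8.33% false. A simulated 1.5-fold shift of all glycolysis genes, with no other list moved, ranked 1 among the lists. Counts were drawn independently between genes with 1 dispersion, 0.0213, for all of them. In the data the glycolysis list had an estimated correlation of 0.57, so this rank says nothing of lists with correlated genes. The shares above likewise hold for the simulated setting alone.

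Alternatives listed before the data were examined were limma without a trend, scaling to a common upper quartile, no filter, a mean of at least 10, a pseudocount of 0.1, the replicate number as a block, fits to the compared groups alone, a fold of at least 2, and leaving out each library. Those chosen after seeing the data were quantile normalisation, library weights, limma-voom on the recovered reads, the muscle list's mean as a covariate, and, for the list tests, leaving out control 0.5 M replicate 1. On the recovered reads, voom called 1110 and 1836 genes for the EcR RNAi label on 0.15 M and 0.5 M sucrose. It called 166 and 2461 genes for diet in controls and in libraries labelled EcR RNAi, and 363 for the interaction. Data handling used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.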

Results

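Fat body RNA was sequenced from female wandering larvae of 2 genotypes on 2 diets, with 3 libraries in each of the 4 groups. The driver r4-GAL4 is active in the fat body, UAS-Dcr2 is used to strengthen RNAi, and EcR encodes the nuclear receptor for the moulting hormone ecdysone. The questions were how the EcR RNAi label, the high-sugar diet of 0.5 M sucrose and their combination related to gene expression. Values are a normalised signal per gene for 10047 genes, and the reads recovered from it summed to between 8520039 and 11598357 per library. Correlations of log2 values lay between 0.967 and 0.984 within groups and between 0.91 and 0.978 across groups. Control 0.5 M replicate 1 stood apart, with a signal sum of 15045575 against 8864826 to 10966639 in the other libraries, 47.8% of that sum in its 10 highest genes, and the largest deviation from its group mean, 0.415 (root mean square of log2 values) against 0.279 to 0.361 in the others. The labels do not say whether libraries came from separate crosses, so p-values measure the spread between these samples, which may be technical in part.

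EcR itself (FBgn0000546) did not differ detectably between genotypes. On 0.15 M sucrose its signal was 1380.0 ± 173 (SD, n = 3) in controls and 1132 ± 106 (n = 3) in the libraries labelled EcR RNAi, a log2 difference of -0.28 with a 95% interval from -0.65 to 0.08 (limma, Benjamini-Hochberg adjusted p = 0.386). On 0.5 M sucrose the values were 1454 ± 64.2 and 1414 ± 328, a difference of -0.06 with an interval from -0.43 to 0.30 (limma, Benjamini-Hochberg adjusted p = 0.847). Without EcRi 0.5 M replicate 3 the difference on 0.5 M was 0.09. The marker gene w, which RNAi transgenes usually carry, rose by 0.75 ± 0.19 (log2, SE) on 0.15 M and 0.77 ± 0.19 on 0.5 M (limma, Benjamini-Hochberg adjusted p = 0.0132 and 0.00797). Without control 0.15 M replicate 1 the first of these had an adjusted p of 0.0629 (limma, Benjamini-Hochberg). Within each diet all 3 libraries labelled EcR RNAi lay above all 3 controls for w, though control 0.5 M replicate 1, at 1388, lay above the EcRi 0.15 M libraries, at 1260 to 1294. Dcr-2, whose transgene both genotypes received, differed by -0.32 ± 0.23 and 0.48 ± 0.23 (limma, Benjamini-Hochberg adjusted p = 0.486 and 0.174). Directions given below are therefore those of the libraries labelled EcR RNAi.

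On 0.15 M sucrose, 9 of 17 immune effector genes rose and 1 fell in the libraries labelled EcR RNAi, 7 of 21 lipogenesis genes rose, and of 24 ecdysone response genes 10 fell and 1 rose. The lists had adjusted p = 0.466, 0.589 and 0.538 with an estimated correlation (limma camera, Benjamini-Hochberg). IM3 (FBgn0040736), an immune-induced peptide, rose from 29.1 ± 13.7 to 1297 ± 443 (SD, n = 3 each), and Drs (FBgn0010381), the antifungal peptide drosomycin, from 612 ± 164 to 9577 ± 778. ACC (FBgn0033246), the enzyme of the committed step of fatty acid synthesis, rose from 1931 ± 473 to 8787 ± 1701. E23 (FBgn0020445), an ecdysone-induced transporter gene, fell from 972 ± 250.4 to 231 ± 37.7. The scavenger receptor gene santa-maria fell from 449 ± 190 to 14.0 ± 8.11. In all, limma called 1125 genes at Benjamini-Hochberg adjusted p under 0.05, of which 622 were higher and 503 lower, and 636 also changed at least 2-fold. The 3 libraries of one group lay beyond the 3 of the other for 28% of genes, where chance gives 10%.

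Among called genes whose groups did not overlap and whose higher mean was at least 10, the largest rises were those of CG16836 at 6.64 ± 0.57 (log2, SE), CG15068 at 6.02 ± 0.42, IM3 at 5.50 ± 0.57, CG43133 at 5.37 ± 0.45 and CG14752 at 4.97 ± 0.16 (limma, Benjamini-Hochberg adjusted p from 8.21e-12 to 0.000201). Besides santa-maria at -5.00 ± 0.50, large falls were those of dro5, a drosomycin-like peptide, at -4.99 ± 0.66, nimC2, a nimrod receptor, at -4.53 ± 0.22, and CG3397 at -4.49 ± 0.39 (limma, Benjamini-Hochberg adjusted p from 2.26e-09 to 0.000509). Of the salivary gland genes given below, Eig71Ee fell by more than santa-maria and Sgs4 by more than nimC2. All 16 leading genes kept their call in each fit that left out 1 library. Of all 61 calls that the naming rule gave here, list members included, 55 were kept in each such fit. CG16836, CG15068 and IM3, now named BomT2, BomS6 and BomS3, belong to 1 family of short genes, and since the counting is not given in the sources used here, reads shared between members or with overlapping genes leave their single values uncertain.

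Lists are led here by their counts of genes, since camera at the preset correlation also called many lists when the libraries were grouped in other ways. A list's count is to be read beside the number called among all 10047 genes in the same comparison. Here these were 622 higher and 503 lower. Of 24 measured ecdysone response genes, 10 fell and 1 rose (11 and 3 adjusted over the list alone). Eip78C and Eip75B, which encode nuclear receptors, fell by 1.79 and 1.48 on the log2 scale, and ftz-f1, a nuclear receptor gene of the mid-prepupal response, rose by 0.99. Camera gave this list an adjusted p of 0.000544 (limma, Benjamini-Hochberg), and adjusted p = 0.538 with an estimated correlation. Of 17 measured immune effectors, 9 rose and 1, PGRP-SB1, fell (11 and 1 adjusted over the list alone). PGRP-SC2 rose by 3.47 ± 0.25, TotC by 4.68 ± 0.46 and TotA by 2.85 ± 0.27, and the list had camera adjusted p = 7.39e-08 (limma, Benjamini-Hochberg) and adjusted p = 0.466 with an estimated correlation. In the lipogenesis list 7 of 21 genes rose and 0 fell (7 and 0 adjusted over the list alone), including AcCoAS, acetyl-CoA synthetase, by 1.78 and mdy, a diacylglycerol acyltransferase, by 1.48. Its camera adjusted p was 0.000544 (limma, Benjamini-Hochberg), with adjusted p = 0.589 with an estimated correlation.

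Among pentose phosphate and polyol genes 4 of 10 rose (5 adjusted over the list alone), with Pepck, an enzyme of gluconeogenesis, at 1.32 ± 0.23, camera adjusted p = 0.00331 (limma, Benjamini-Hochberg) and adjusted p = 0.617 with an estimated correlation. Zw and Pgd, at 0.75 ± 0.19 and 0.77 ± 0.20, had adjusted p of 0.0866 without control 0.15 M replicate 1 and 0.111 without control 0.15 M replicate 3 (limma, Benjamini-Hochberg). Autophagy genes went both ways, with 1 of 22 higher, Atg4, and 4 lower (1 and 9 adjusted over the list alone). Atg7, the activating enzyme of autophagy, fell by 2.44, and the list had camera adjusted p = 0.000544 (limma, Benjamini-Hochberg) and adjusted p = 0.589 with an estimated correlation. In the lipolysis and fatty acid oxidation list 1 of 18 rose and 2 fell (1 and 2 adjusted over the list alone), bmm, a triglyceride lipase, by 0.83, with camera adjusted p = 0.0344 (limma, Benjamini-Hochberg) and adjusted p = 0.744 with an estimated correlation. With genes limited to a mean of at least 10 this camera p was 0.0632. The insulin and TOR list held 1 higher and 4 lower genes among 24 (2 and 6 adjusted over the list alone, camera adjusted p = 0.159, limma with Benjamini-Hochberg). Its members Ilp6, an insulin-like peptide made by the fat body, and Thor, a translation repressor, fell from 1249 ± 147 to 307 ± 16.0 and from 778 ± 181 to 189 ± 35.6 (SD, n = 3 each).

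Markers of other tissues moved with the genotype as well. Of 8 measured salivary gland genes 7 fell, among them Sgs3 at -4.02 ± 0.43, Sgs4 at -4.95 ± 0.70 and Eig71Ee at -5.59 ± 0.77 (7 adjusted over the list alone), with camera adjusted p = 3.75e-08 (limma, Benjamini-Hochberg) and adjusted p = 0.427 with an estimated correlation. The 13 muscle genes had a median of -1.13, and 0 of them passed in limma or in voom, 0 also adjusted over the list alone, against 4 at an unadjusted p under 0.05, with camera adjusted p = 6.46e-05 (limma, Benjamini-Hochberg) and adjusted p = 0.619 with an estimated correlation. The muscle genes of smallest p were bt at -1.08 ± 0.36 and Act87E at -1.14 ± 0.43 (limma, Benjamini-Hochberg adjusted p = 0.0832 and 0.142). In the ring gland list sad, an enzyme of ecdysone synthesis, rose from 219 ± 76.9 to 1176 ± 253 (SD, n = 3 each), and the other 5 genes did not pass over all genes. Adjusted over the list alone 2 genes of this list were higher and 1 lower.

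**Figure D1:**
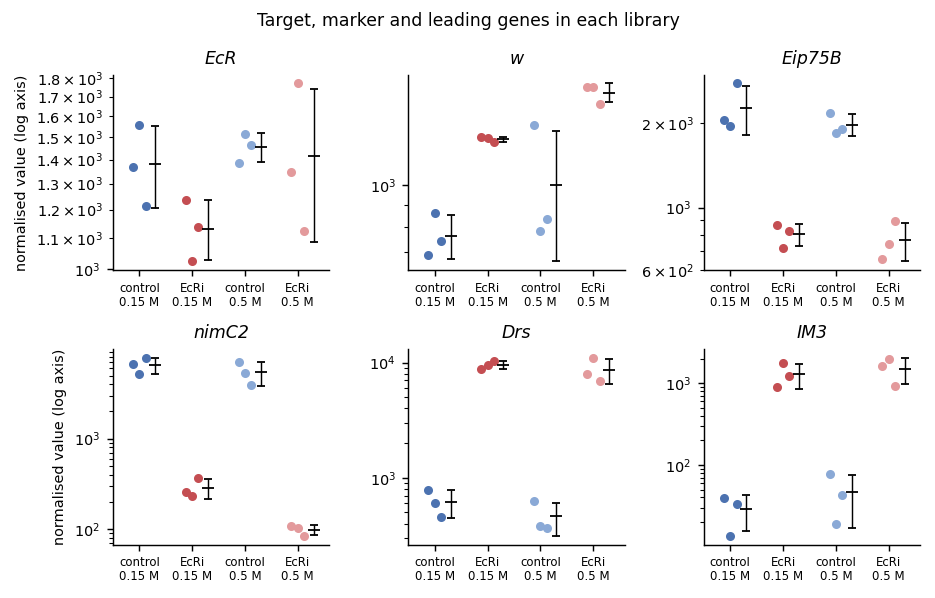
Normalised signal (log axis) of EcR, w, Eip75B, nimC2, Drs and IM3 in each library of the 4 groups, where EcRi stands for the EcR RNAi label, points are libraries and the black mark is the mean ± SD of 3. Drs lay at 612 ± 164 in controls and 9577 ± 778 in EcRi on 0.15 M sucrose, while EcR lay at 1380.0 ± 173 and 1132 ± 106.

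On 0.5 M sucrose, 8 of 17 immune effector genes and 9 of 21 lipogenesis genes rose in the libraries labelled EcR RNAi, with 1 of each list falling, and of 14 chaperone genes 5 fell and 1 rose. All 3 lists had adjusted p = 0.691 with an estimated correlation (limma camera, Benjamini-Hochberg). ACC rose from 2710.0 ± 512 in controls to 19700 ± 1972 (SD, n = 3 each), CG3523 (FBgn0027571), a fatty acid synthase, from 10550 ± 863 to 50930 ± 5877, and Men (FBgn0002719), malic enzyme, from 3331 ± 628 to 18760 ± 174. Drs rose from 461 ± 147 to 8605 ± 2137. Hsp23 (FBgn0001224) fell from 20690 ± 3734 to 1382 ± 368, and nimC2 from 5423 ± 1566 to 98.1 ± 12.2. limma called 1915 genes at Benjamini-Hochberg adjusted p under 0.05, 1100 higher and 815 lower, of which 923 changed at least 2-fold. The 2 groups lay apart for 35.6% of genes, where chance gives 10% on average. Scaling to a common upper quartile changed the split to 913 higher and 1043 lower, from 57.4% to 46.7% higher, and with library weights 3628 genes were called.

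By the same rule the largest rises on 0.5 M sucrose were CG32557 at 6.0 ± 0.31 (log2, SE), Cyp309a2 at 5.93 ± 0.46, CG11898 at 5.67 ± 0.60, CG15068 at 5.60 ± 0.42 and CG13135 at 5.56 ± 0.62 (limma, Benjamini-Hochberg adjusted p from 3.05e-08 to 0.000257). The largest falls were nimC2 at -5.74 ± 0.22, CG3397 at -4.76 ± 0.39, CG31100 at -4.33 ± 0.30 and CG15369 at -4.25 ± 0.47 (limma, Benjamini-Hochberg adjusted p from 7.84e-11 to 0.000104). Each of the 16 leading genes kept its call without any single library. Of all 81 calls that the naming rule gave here, list members included, 68 were kept in each such fit.

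In the lipogenesis list 9 of 21 genes rose and 1, CG4729, fell (10 and 1 adjusted over the list alone), with camera adjusted p = 0.00147 (limma, Benjamini-Hochberg) and adjusted p = 0.691 with an estimated correlation. Of 14 glycolytic genes 5 rose (7 adjusted over the list alone), Hex-C, a hexokinase, by 2.79 ± 0.22 and PyK, pyruvate kinase, by 1.29 ± 0.18. That list had camera adjusted p = 0.00147 (limma, Benjamini-Hochberg) and adjusted p = 0.691 with an estimated correlation. Of 24 insulin and TOR genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), with Pi3K92E, the catalytic subunit of phosphoinositide 3-kinase, at 2.04 ± 0.13, Sesn at 1.44 ± 0.15 and S6k at 1.18 ± 0.14. With upper quartile scaling 8 rose and 2 fell, and after quantile normalisation 7 and 2. The list includes both activators and repressors of the pathway, and had camera adjusted p = 0.00544 (limma, Benjamini-Hochberg) and adjusted p = 0.691 with an estimated correlation. Immune effectors counted 8 higher and 1 lower of 17 (8 and 1 adjusted over the list alone), with camera adjusted p = 0.00287 (limma, Benjamini-Hochberg) and adjusted p = 0.691 with an estimated correlation. Of 14 chaperones 5 fell and 1, Xbp1, rose (8 and 1 adjusted over the list alone), including Hsp23 at -3.92 ± 0.33 and Hsp27 at -2.0 ± 0.28. Hsp23 was lower on 0.15 M too, at -1.82 ± 0.33, the 1 of 14 chaperones that fell there while 2 rose (1 and 2 adjusted over the list alone; camera adjusted p = 0.68, limma with Benjamini-Hochberg). On 0.5 M the chaperones had camera adjusted p = 0.00362 (limma, Benjamini-Hochberg) and adjusted p = 0.691 with an estimated correlation.

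Ecdysone response genes on 0.5 M sucrose split into 5 higher and 8 lower of 24 (5 and 9 adjusted over the list alone; camera adjusted p = 0.0694, limma with Benjamini-Hochberg). E23 at -1.98 ± 0.18, Eip78C at -1.69 ± 0.17 and Eip75B at -1.38 ± 0.17 were among the lower ones, and ImpL1 at 2.41 and Cyp18a1, an ecdysone-inactivating enzyme, at 1.88 among the higher. In the larval serum protein list Lsp1alpha and Fbp1 fell, 2 of 6 genes (2 adjusted over the list alone), Lsp1alpha by 2.53 and Fbp1 by 1.38 on the log2 scale, and the list was not called (camera adjusted p = 0.29, limma with Benjamini-Hochberg). The 87 cytoplasmic ribosomal protein genes had a median of -0.14, with 0 higher and 2 lower (0 adjusted over the list alone), camera adjusted p = 0.0245 (limma, Benjamini-Hochberg) and adjusted p = 0.835 with an estimated correlation. Without control 0.5 M replicate 1 that median was 0.10, with adjusted p = 0.304.

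Salivary gland genes were lower here too, 4 of 8 (6 lower and 1 higher adjusted over the list alone), with Sgs4 at -4.21 ± 0.70 and Eig71Ee at -4.17 ± 0.77, camera adjusted p = 0.00147 (limma, Benjamini-Hochberg) and adjusted p = 0.691 with an estimated correlation. Sgs3, at -1.74 ± 0.43, lost its call without control 0.5 M replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.0656). Muscle genes had 0 of 13 past the test in limma or voom, 0 also adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.239, limma with Benjamini-Hochberg). Enzymes of ecdysone synthesis in the ring gland list went both ways. The gene sad rose from 252 ± 60.9 to 7287 ± 741 (SD, n = 3 each), while spok fell from 64.4 ± 36.3 to 5.27 ± 1.16, and phm, nvd and sro fell as well, so that 1 rose and 4 fell of 6 (1 and 4 adjusted over the list alone; camera adjusted p = 0.233, limma with Benjamini-Hochberg).

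The comparisons of genotype on the 2 diets share no library, but both use 1 estimate of each gene's spread from all 12 libraries. Genes of low spread are thus more readily called in both, and the counts for independent lists may be too low. Of the genes called, 417 rose and 265 fell on both diets, where independent lists would share 68.1 and 40.8, and 12 were called in opposite directions. Genes shared in this way included IM3, Drs, ACC, E23, Eip75B, nimC2 and sad. Across genes, which are not independent replicates, the fold changes on the 2 diets had Pearson r = 0.544 and Spearman rho = 0.252.

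**Figure D2:**
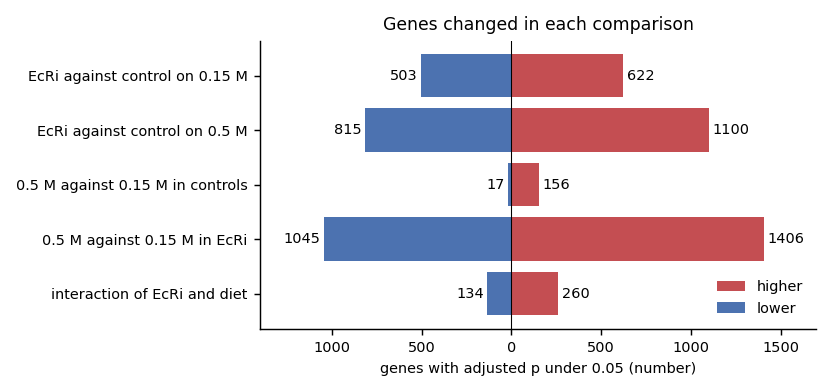
Number of genes with limma adjusted p under 0.05 in each of the 5 comparisons, higher to the right and lower to the left of 0, with EcRi standing for the EcR RNAi label and higher, for the interaction, meaning a larger log2 diet change in EcRi than in controls. Diet gave 173 genes in controls, 90.2% of them higher, and 1406 higher and 1045 lower in EcRi.

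In controls, 0.5 M sucrose went with higher mRNA of a small number of genes. Cyp4e3 (FBgn0015035), a cytochrome P450, rose from 30.1 ± 4.70 to 740.0 ± 305 (SD, n = 3 each), CG6074 (FBgn0039486) from 9.31 ± 2.31 to 82.7 ± 7.94, and CG14275 from 14.6 ± 3.90 to 121 ± 31.1. Pgd and Zw, the oxidative enzymes of the pentose phosphate pathway, rose from 1224 ± 207 to 2679 ± 703 and from 107 ± 24.7 to 211 ± 16.6. limma called 173 genes at Benjamini-Hochberg adjusted p under 0.05, 17 of them lower and the other 90.2% higher, and 109 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 1443 genes. With library weights 968 genes were called, 626 higher and 342 lower, or 64.7% higher. The groups lay apart for 18% of genes, where chance gives 10%.

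This count moved with single libraries. It was 74 without control 0.15 M replicate 3, 103 without control 0.15 M replicate 2, 105 without control 0.5 M replicate 1, 84 without control 0.5 M replicate 3 and 359 without control 0.5 M replicate 2. It was 62 without a trend and 60 in a fit to the compared groups alone. Of the 16 leading genes 7 kept their call without any single library, among them Cyp4e3 at 4.51 ± 0.29 (log2, SE), CG6074 at 3.04 ± 0.27, CG14275 at 2.96 ± 0.27, ng3 at 2.96 ± 0.35 and Iris at 2.91 ± 0.41 (limma, Benjamini-Hochberg adjusted p from 6e-06 to 0.00348). Calls that ended in such fits included CG3348 at 3.71 ± 0.68 and CG3264 at -3.0 ± 0.68, with highest adjusted p of 0.126 without control 0.15 M replicate 3 and 0.135 without control 0.15 M replicate 2 (limma, Benjamini-Hochberg).

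In the lipogenesis list 3 of 21 genes rose (7 adjusted over the list alone), with desat1, a fatty acid desaturase, at 1.28 ± 0.25 and AcCoAS at 1.06 ± 0.22, camera adjusted p = 5.04e-05 (limma, Benjamini-Hochberg) and adjusted p = 0.551 with an estimated correlation. Without control 0.15 M replicate 3 desat1 and AcCoAS had adjusted p of 0.0862 and 0.105, and the other called gene, CG4729 at 0.71 ± 0.16, had 0.123 (limma, Benjamini-Hochberg). Lipolysis and fatty acid oxidation counted 2 of 18 higher, scu and Mtpalpha (9 higher and 1 lower adjusted over the list alone), camera adjusted p = 3.83e-06 (limma, Benjamini-Hochberg) and adjusted p = 0.551 with an estimated correlation. Without control 0.15 M replicate 2 scu and Mtpalpha had adjusted p of 0.138 and 0.184. In the pentose phosphate and polyol list 2 of 10 rose (6 adjusted over the list alone), Pgd at 1.11 ± 0.20 and Zw at 1.0 ± 0.19, camera adjusted p = 5.73e-05 (limma, Benjamini-Hochberg) and adjusted p = 0.551 with an estimated correlation. Pgd had adjusted p = 0.061 without control 0.15 M replicate 3, and Zw 0.0575 without control 0.5 M replicate 3. Glycogen and trehalose genes counted 1 higher of 10, CG33138 (2 adjusted over the list alone), camera adjusted p = 0.00241 (limma, Benjamini-Hochberg) and adjusted p = 0.585 with an estimated correlation. CG33138, at 1.08 ± 0.23, had adjusted p = 0.126 without control 0.15 M replicate 3.

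In several further lists camera passed while 0 genes did, in limma over all genes, in limma adjusted over the list alone and in voom. At an unadjusted p under 0.05 there were 31 of the 87 cytoplasmic ribosomal proteins, 5 of 24 genes of oxidative phosphorylation, 4 of 14 of glycolysis, and 3 each of the lysosome, ecdysone response and cell cycle lists. Medians were 0.39 for the 87 cytoplasmic ribosomal proteins, 0.25 for oxidative phosphorylation and 0.34 for glycolysis, with camera adjusted p of 4.58e-13, 0.00016 and 0.0215 (limma, Benjamini-Hochberg) and adjusted p = 0.585, 0.637 and 0.682 with an estimated correlation. Quantile normalisation gave camera adjusted p of 0.244 for glycolysis and 0.0591 for oxidative phosphorylation, and leaving out control 0.5 M replicate 1 gave 0.0932 for glycolysis and 0.143 for the cell cycle (limma, Benjamini-Hochberg). For lysosome the median was 0.15, and -0.01 after quantile normalisation, with camera adjusted p = 0.0287 (limma, Benjamini-Hochberg) and adjusted p = 0.585 with an estimated correlation. Medians were -0.29 for the ecdysone response and -0.30 for the cell cycle, with camera adjusted p of 0.00241 and 0.000303 (limma, Benjamini-Hochberg) and adjusted p = 0.551 and 0.585 with an estimated correlation. Midgut genes had a median of 0.79, 0 of 12 past the test in limma or voom over all genes, 1 adjusted over the list alone and 3 at an unadjusted p under 0.05, camera adjusted p = 0.00329 (limma, Benjamini-Hochberg) and adjusted p = 0.585 with an estimated correlation.

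In the libraries labelled EcR RNAi, 0.5 M sucrose went with higher mRNA of 14 of 24 insulin and TOR genes, 12 of 21 lysosome genes and 10 of 22 autophagy genes, while 6 of 14 chaperones fell and 1 rose. After quantile normalisation the first 3 lists had 8, 4 and 7 higher genes, and the 4 lists had adjusted p = 0.36, 0.36, 0.426 and 0.36 with an estimated correlation (limma camera, Benjamini-Hochberg). Ilp6 (FBgn0044047) rose from 307 ± 16.0 to 1243 ± 205 (SD, n = 3 each), Thor (FBgn0261560) from 189 ± 35.6 to 804 ± 172 and Pi3K92E (FBgn0015279) from 555 ± 44.7 to 1703 ± 33.2. The lipase gene bmm rose from 151 ± 9.56 to 383 ± 19.3, and Mio, a sugar-responsive transcription factor, from 543 ± 125 to 1682 ± 337. Hsp26 fell from 2316 ± 648 to 492 ± 73.1, and spok from 139 ± 48.9 to 5.27 ± 1.16. Muscle markers moved with these groups, 8 of 13 being higher. limma called 2451 genes at Benjamini-Hochberg adjusted p under 0.05, 1406 higher and 1045 lower, of which 993 changed at least 2-fold, 349 higher and 644 lower. The groups lay apart for 44.7% of genes, where chance gives 10% on average.

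Scaling to a common upper quartile moved the median of all genes from -0.02 to -0.23 in this comparison, and the split to 773 higher and 1792 lower, from 57.4% to 30.1% higher. The count was 1355 without EcRi 0.5 M replicate 1, 1431 without EcRi 0.15 M replicate 2, and 309 with the muscle list's mean as a covariate. By the naming rule the largest rises were Cyp4e3 at 5.80 ± 0.29 (log2, SE), CG1077 at 5.80 ± 0.62, CG11898 at 4.66 ± 0.60, Cpr47Eb, a cuticle protein gene, at 4.34 ± 0.85 and CG3348 at 3.98 ± 0.68 (limma, Benjamini-Hochberg adjusted p from 3.98e-07 to 0.00441). The largest falls were spok at -4.44 ± 0.44, CG15369 at -3.20 ± 0.47 and CG1722 at -3.0 ± 0.46 (limma, Benjamini-Hochberg adjusted p from 2.61e-05 to 0.00119). Of the 16 leading genes 15 kept their call without any single library, and CG14332, at -2.80 ± 0.74, had adjusted p = 0.0979 without EcRi 0.5 M replicate 1 (limma, Benjamini-Hochberg). Of all 83 calls that the naming rule gave here, list members included, 64 were kept in each such fit. Calls of list members given below may thus rest on 1 library.

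Lists with most of their called genes higher are given with the counts at the deposited scaling, at a common upper quartile and after quantile normalisation. Insulin and TOR signalling had 14 of 24 higher and 0 lower (17 adjusted over the list alone), then 9 higher and 1 lower, then 8 and 1, with camera adjusted p = 1.24e-06 (limma, Benjamini-Hochberg) and adjusted p = 0.36 with an estimated correlation. Lysosome had 12 of 21 higher and 0 lower (12 adjusted over the list alone), then 8 and 1, then 4 and 1, with Vha55, a proton pump subunit, at 1.09 ± 0.16, camera adjusted p = 6.99e-05 (limma, Benjamini-Hochberg) and adjusted p = 0.36 with an estimated correlation. Lipolysis and fatty acid oxidation had 11 of 18 higher (15 adjusted over the list alone), then 10, then 10, with bmm at 1.34 ± 0.17, camera adjusted p = 1.44e-07 (limma, Benjamini-Hochberg) and adjusted p = 0.426 with an estimated correlation. Autophagy had 10 of 22 higher (11 adjusted over the list alone), then 6, then 7, with Atg2 at 0.92 ± 0.16, camera adjusted p = 0.000633 (limma, Benjamini-Hochberg) and adjusted p = 0.426 with an estimated correlation. Lipogenesis had 10 of 21 higher and 1 lower (11 and 1 adjusted over the list alone), then 7 and 2, then 8 and 1, with Men at 1.53 ± 0.21 and CG3523 at 1.54 ± 0.23, camera adjusted p = 0.000811 (limma, Benjamini-Hochberg) and adjusted p = 0.426 with an estimated correlation. Muscle had 8 of 13 higher (11 adjusted over the list alone), then 5, then 1, with Act87E at 1.95 ± 0.43, camera adjusted p = 7.4e-06 (limma, Benjamini-Hochberg) and adjusted p = 0.426 with an estimated correlation.

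Glycolysis counted 8 of 14 higher, with Pfrx at 1.32 ± 0.19, the TCA cycle 7 of 12, with skap at 1.29 ± 0.18, glycogen and trehalose 7 of 10, with Tret1-1, a trehalose transporter, at 0.97 ± 0.20, and oxidative phosphorylation 6 of 24, with SdhB at 0.67 ± 0.15. Adjusted over the list alone these counts were 9 higher, 7 higher and 1 lower, 7 higher, and 8 higher. Over all 10047 genes 2451 were called in this comparison, 1406 of them higher. The 6 of 24 called in oxidative phosphorylation are thus near the share of all genes called in either direction. Sugar sensing had 5 of 11 higher (5 adjusted over the list alone), with Mio at 1.64 ± 0.18, and pentose phosphate and polyol 4 of 10 (4 adjusted over the list alone), with Zw at 1.81 ± 0.19. Camera adjusted p for these 6 lists ran from 6.75e-05 for glycolysis to 0.0253 for pentose phosphate and polyol (limma, Benjamini-Hochberg), and adjusted p from 0.426 to 0.567 with an estimated correlation. After quantile normalisation glycogen and trehalose had 3 higher genes and the TCA cycle 4 higher and 1 lower. It left oxidative phosphorylation at 2 higher genes and camera adjusted p = 0.496, and pentose phosphate and polyol at 3 higher and 1 lower with 0.156 (limma, Benjamini-Hochberg). Of 14 chaperones 6 fell and 1 rose (7 and 1 adjusted over the list alone), with Hsp23 at -2.26 ± 0.33, Hsp27 at -1.91 ± 0.28 and Hsp26 at -2.21 ± 0.33, camera adjusted p = 0.00512 (limma, Benjamini-Hochberg) and adjusted p = 0.36 with an estimated correlation. In the salivary gland list 2 of 8 rose (2 adjusted over the list alone), ng3 at 3.64 ± 0.35 and Sgs3 at 1.76 ± 0.43, camera adjusted p = 0.0331 (limma, Benjamini-Hochberg) and adjusted p = 0.526 with an estimated correlation. Sgs3 had adjusted p = 0.0657 without EcRi 0.5 M replicate 1, and with genes limited to a mean of at least 10 the list's camera p was 0.0539 (limma, Benjamini-Hochberg).

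**Figure D3:**
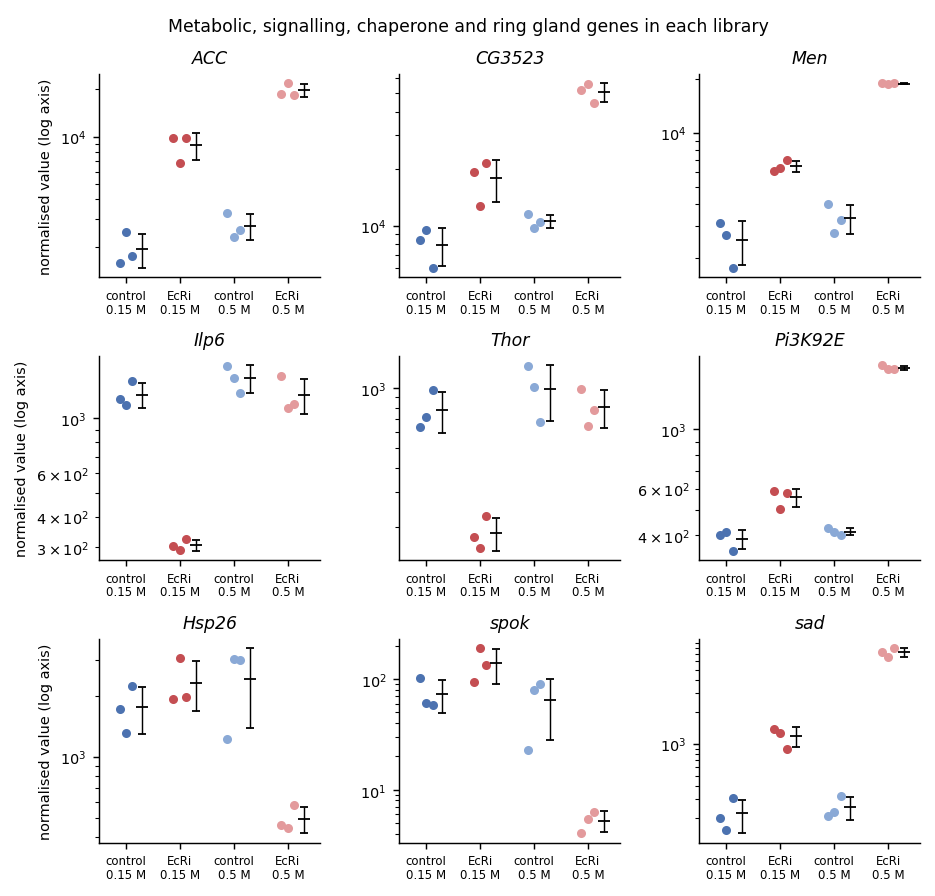
Normalised signal (log axis) of ACC, CG3523, Men, Ilp6, Thor, Pi3K92E, Hsp26, spok and sad in each library of the 4 groups, where EcRi stands for the EcR RNAi label, points are libraries and the black mark is the mean ± SD of 3. Ilp6 lay at 1249 ± 147 and 1454 ± 186 in controls on 0.15 M and 0.5 M sucrose, and at 307 ± 16.0 and 1243 ± 205 in EcRi.

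The diet comparisons in the 2 genotypes share no library either, though they too share each gene's estimate of spread. They had 105 higher and 8 lower genes in common, where independent lists would share 21.8 and 1.8, and 2 genes were called in opposite directions. Without a trend 46 genes were shared in direction. Cyp4e3, CG6074, ng3, Pgd, Zw and AcCoAS were called higher in both. Across genes the diet fold changes had Pearson r = 0.406 and Spearman rho = 0.353.

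The interaction tested directly whether the diet change differed between genotypes. Ilp6 differed by 1.79 ± 0.22 (log2, SE), Thor by 1.75 ± 0.34 and Pi3K92E by 1.52 ± 0.18, with larger diet changes in the libraries labelled EcR RNAi (limma, Benjamini-Hochberg adjusted p = 0.000581, 0.0121 and 0.000502). In the ring gland list sad differed by 2.42 ± 0.33, spok by -4.08 ± 0.62 and phm by -2.34 ± 0.44 (limma, Benjamini-Hochberg adjusted p = 0.00181, 0.00426 and 0.0122). Hsp26 and Hsp68 differed by -2.59 ± 0.46 and -2.21 ± 0.41 (limma, Benjamini-Hochberg adjusted p = 0.0115 and 0.0121). In all, limma called 394 genes, 260 positive and 134 negative, of which 264 had a difference of at least 2-fold. Of these genes 371 were called for diet in the libraries labelled EcR RNAi, 21 in controls and 8 in both. By their estimates, whether called or not, 362 had the larger diet change in the libraries labelled EcR RNAi. The estimates of 276 had opposite signs in the 2 genotypes, which does not show that both changed.

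The interaction count was 141 without EcRi 0.5 M replicate 1, 151 without EcRi 0.15 M replicate 2, 183 without control 0.15 M replicate 2 or control 0.5 M replicate 3, 239 without control 0.15 M replicate 3, 242 without EcRi 0.15 M replicate 1 and 248 without EcRi 0.5 M replicate 3. It was 136 without a trend, 260 with the replicate number as a block, 1546 with library weights and 47 with the muscle mean as a covariate. Upper quartile scaling moved the median of all genes from -0.05 to -0.17 and the split to 139 positive and 209 negative, from 66% to 39.9% positive, and quantile normalisation gave 187 and 186, or 50.1%. Of the 10 leading genes CG14515 at 4.32 ± 0.80, CG10814 at 3.76 ± 0.52, spok, CG15369 at -3.65 ± 0.67 and CG42715 at -3.48 ± 0.69 kept their call without any single library (limma, Benjamini-Hochberg adjusted p from 0.00379 to 0.0177).

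Insulin and TOR signalling had 7 of 24 genes with a positive interaction (14 positive and 1 negative adjusted over the list alone), camera adjusted p = 3.55e-07 (limma, Benjamini-Hochberg) and adjusted p = 0.167 with an estimated correlation. Chaperones had 4 of 14 negative (4 adjusted over the list alone), camera adjusted p = 0.00015 (limma, Benjamini-Hochberg) and adjusted p = 0.167 with an estimated correlation. The muscle list had a median of 1.66 with 0 of 13 past the test in limma or voom, 0 also adjusted over the list alone and 5 at an unadjusted p under 0.05, camera adjusted p = 1.17e-05 (limma, Benjamini-Hochberg) and adjusted p = 0.713 with an estimated correlation. The 6 ring gland genes had 1 positive and 2 negative (1 and 3 adjusted over the list alone), camera adjusted p = 0.0497 (limma, Benjamini-Hochberg) and adjusted p = 0.66 with an estimated correlation, while upper quartile scaling gave 0.0904 and a mean of at least 10 gave 0.0548. Autophagy had 1 of 22 positive, Atg2, and lysosome 1 of 21, Vha55 (5 and 8 adjusted over the list alone), camera adjusted p = 0.00028 and 0.0084 (limma, Benjamini-Hochberg) and adjusted p = 0.66 for both with an estimated correlation. Quantile normalisation gave 0.0512 for lysosome (limma, Benjamini-Hochberg). Without EcRi 0.5 M replicate 1 Atg2 and Vha55 had adjusted p of 0.0779 and 0.0996.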

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

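Of the tests in this part, the list tests without control 0.5 M replicate 1, the choice of that library for weighing out of the planned fits without each library, the comparison of other tissues with muscle and the muscle covariate were chosen after the result was seen, and the criterion for the other tissues was changed after its first form had decided nothing and again after its second had left out the spread between libraries. Groups of 3 libraries were not tested for outlying samples. The results below stand out because the diet change differed between the libraries labelled EcR RNAi and the controls by a test of the difference itself.

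limma gave 394 genes with a diet change that differed between genotypes (Benjamini-Hochberg adjustment). In 100 permutations of the residuals of a model without the interaction, the real order included, 1 reached this count, and the highest of the others was 20. Such residuals still hold any interaction, which widens the spread in the permuted sets and can lower their counts. The real order thus stood out among these permutations, but the gap does not by itself exclude chance for the gene count. For gene lists the real count was 12, the highest other 19, and 30 of the 100 gave as many, so chance cannot be excluded for the list calls.

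Given as the log2 diet change in the libraries labelled EcR RNAi minus that in controls, the largest positive values were 4.33 for CG1077, 4.32 for CG14515, 4.04 for CG5697, 3.76 for CG10814 and 3.68 for CG11898. The largest negative values were -4.08 for spok, -3.65 for CG15369, -3.48 for CG42715, -3.42 for CG15919 and -3.08 for CG9150. In metabolism and signalling the values were 1.79 for Ilp6, 1.75 for Thor, 1.52 for Pi3K92E, 1.26 for Mio, 1.23 for Pfrx, 1.11 for Men and 0.96 for bmm. Atg2 had 1.0, Vha55 0.98 and vri, a clock gene in the ecdysone list, 0.89. Among heat shock genes Hsp26 had -2.59, Hsp68 -2.21 and Hsp27 -1.96. The enzymes of ecdysone synthesis sad and phm had 2.42 and -2.34. The remaining values were -1.99 for PGRP-SB1, -1.79 for deltaTry, a trypsin gene, -1.53 for Cyp9b2, -1.26 for ZnT35C and -1.21 for RpL41.

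Several of these calls ended without 1 library, with highest adjusted p as follows (limma, Benjamini-Hochberg). Without EcRi 0.5 M replicate 1 it was 0.0577 for CG5697 and for Pfrx, 0.0509 for Hsp27, 0.0779 for Atg2, 0.0996 for Vha55, 0.116 for PGRP-SB1, 0.143 for RpL41 and 0.0957 for deltaTry. Without EcRi 0.15 M replicate 2 it was 0.0989 for CG11898, 0.0573 for CG9150 and 0.0649 for vri. Without control 0.5 M replicate 3 it was 0.0575 for CG1077 and 0.0548 for CG15919, and without control 0.15 M replicate 2 it was 0.123 for Men and 0.102 for bmm.

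The lists that camera called for the difference had medians of 0.565 for insulin and TOR signalling, 0.47 for lipolysis and fatty acid oxidation, 0.408 for glycolysis, 0.398 for the TCA cycle, 0.379 for sugar sensing, 0.312 for autophagy and 0.201 for lysosome. Medians were 1.658 for muscle, 0.992 for salivary gland, -0.269 for cytoplasmic ribosomal proteins, -0.854 for chaperones and -1.594 for ring gland. Genes called by limma were 7 of 24 for insulin and TOR signalling and 1 positive each of 18 for lipolysis and fatty acid oxidation, 14 for glycolysis, 11 for sugar sensing, 22 for autophagy and 21 for lysosome, with 4 of 14 chaperones and 1 of 87 cytoplasmic ribosomal proteins negative and 1 of 6 ring gland genes positive and 2 negative. In the TCA cycle, muscle and salivary gland lists limma and voom each called 0 of 12, 13 and 8 genes, against 6, 5 and 1 at an unadjusted p under 0.05 and 1, 0 and 1 adjusted over the list alone. The lists' adjusted p with an estimated correlation ran from 0.167 to 0.884 (limma camera, Benjamini-Hochberg). Without control 0.5 M replicate 1 camera no longer called cytoplasmic ribosomal proteins (adjusted p = 0.447) or salivary gland (0.136).

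More genes changed with diet in the libraries labelled EcR RNAi than in controls, and technical sources may account for part of this. The deviating library control 0.5 M replicate 1 is argued against as the whole cause, since the interaction count was 532 without it. Without it diet gave 2959 genes in libraries labelled EcR RNAi and 105 in controls, against 2451 and 173 with it, so the imbalance grew. The imbalance was smaller with library weights, at 2973 against 968 genes. These weights gave this library 0.241 and replicate 3 of its group 5.886, so the smaller imbalance cannot be credited to this library alone. A part from this library stays open. For a lower share of fat body with all other tissues carried over alike, list means were compared with that of muscle. In 4 of 5 other tissue lists the mean diet change lay below that of muscle by more than 2 SE (from libraries and genes together). Differences were -2.949 ± 1.214 for ring gland, -2.126 ± 0.636 for Malpighian tubule, -1.527 ± 0.587 for nervous system and -1.048 ± 0.475 for midgut. Salivary gland, at -0.566 ± 0.669, was not below by this rule. Ring gland and Malpighian tubule stayed below without any single library. The count was 2 without EcRi 0.15 M replicate 2 or EcRi 0.5 M replicate 1, and 3 without EcRi 0.15 M replicate 1 or EcRi 0.5 M replicate 3. A list's mean also moves when its genes are regulated. Of 6 ring gland genes 1 was called higher and 3 lower, and of 5 tubule genes 1 was called lower. The rule was not adjusted over the 5 lists, so the comparison does not settle this explanation. Another candidate is muscle carried over the dissection and centrifugation. Its 13 genes are in no other list, and Mlc2 lay at 3453 ± 2364 and 13720 ± 5451 (SD, n = 3 each) on the 2 diets with the label. The sizes of the changes argue against muscle as the whole cause. With the muscle mean as a covariate the genes that rose kept a share of 0.84 of their log2 change and those that fell 0.872. Those called for the interaction kept 0.922 of their log2 interaction. Without any single library these shares were at least 0.788, 0.813 and 0.848. The genes were chosen for these changes in the same libraries, so the shares may be too high. The calls were not kept, with 309 genes in libraries labelled EcR RNAi against 224 in controls and 47 for the interaction, as SEs were 1.522 times as large for the diet change and 1.262 times for the interaction by the design alone and median sizes went from 0.718 to 0.603, from 1.174 to 0.932 and from 1.168 to 0.993, so a part from muscle stays open, as does an untested biological difference in the response to the diet.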

How the results depend on the processing

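Quantile normalisation, library weights, voom, the muscle covariate and the lists without control 0.5 M replicate 1 were chosen after seeing the data. Every alternative listed beforehand was run, and no filter moved nothing, as every gene passed. Of 298 named gene values, 292 were still tested with a mean of at least 10 and all kept direction and call, 4 lost their call with a pseudocount of 0.1, 7 with voom, 11 with upper quartile scaling, 19 with the replicate block, 23 after quantile normalisation, 40 without a trend and 86 with the muscle covariate, and 38 of the 265 that could be fitted lost it in fits to the compared groups alone. Demanding a fold of at least 2 leaves fewer genes by its construction: 636 and 923 for genotype on 0.15 M and 0.5 M sucrose, 109 and 993 for diet in controls and in libraries labelled EcR RNAi. For the changes below the cause was not tested, apart from the sizes and SEs given above for the muscle covariate. Without a trend 62 genes changed with diet in controls, 136 in the interaction, and 46 were shared by the diet comparisons. A fit to the compared groups alone gave 60 for diet in controls. Library weights, 0.241 for control 0.5 M replicate 1 and 5.886 for replicate 3 of that group, gave 3628 genes for genotype on 0.5 M, 968 for diet in controls (64.7% higher) and 1546 for the interaction. The muscle covariate gave 309 for diet in libraries labelled EcR RNAi, 224 in controls and 47 for the interaction. Leaving out single libraries gave 824 to 1436 and 1318 to 1954 genes for genotype on 0.15 M and 0.5 M, 74 to 359 and 1355 to 2959 for diet in controls and in libraries labelled EcR RNAi, and 141 to 532 for the interaction. With an estimated correlation camera called 0 lists in all 5 comparisons, from 8, 7, 12, 14 and 12. Without control 0.5 M replicate 1 camera called 14 lists for genotype on 0.5 M, and the median of cytoplasmic ribosomal proteins was 0.097 in place of -0.145. Values that had passed no test changed sign. EcR ran from -0.239 to 0.088 for genotype on 0.5 M and from -0.007 to 0.173 for diet in controls over the fits without 1 library. For diet in controls EcR was also -0.007 with upper quartile scaling and -0.087 after quantile normalisation, which gave -0.017 in libraries labelled EcR RNAi. The interaction of w ran from -0.139 to 0.275 without 1 library, and was -0.106 with upper quartile scaling, -0.139 after quantile normalisation and -0.002 with voom. Replicate numbers did not pair the libraries: deviations of the 18 same-numbered pairs correlated from -0.196 to 0.165, 2 of them over 0.1, and 2 of the 12 libraries had their highest correlation with a library of their own number. With the replicate number as a block 1047, 1813, 171, 2272 and 260 genes were called in the 5 comparisons, and all 53 list calls held. With 8520039 to 11598357 recovered reads per library and 3 libraries per group, changes of 1.5-fold were recovered for 22.4% of simulated genes on 0.15 M. That simulation used 1 dispersion for all genes.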

Other observations

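Of the tests in this part, those of the labels, of reads from the hairpin and of the ratios between glue genes were chosen after the result was seen. In the hemocyte list 3 of 12 genes were higher with the EcR RNAi label on 0.15 M sucrose (3 adjusted over the list alone), vkg and Cg25C, the type IV collagen genes, at 1.39 ± 0.17 and 1.35 ± 0.20 (log2, SE) and Pxn, a peroxidase of the matrix, at 0.80 ± 0.17 (camera adjusted p = 0.207, limma with Benjamini-Hochberg; adjusted p = 0.744 with an estimated correlation). The larval fat body is itself a source of type IV collagen, so vkg and Cg25C do not tell hemocytes from fat body. On 0.5 M sucrose vkg, Cg25C, Pxn and crq were higher, 4 of 12 (4 higher and 1 lower adjusted over the list alone), and vkg and Cg25C had adjusted p of 0.064 without EcRi 0.5 M replicate 1 and 0.0593 without control 0.5 M replicate 3 (limma, Benjamini-Hochberg). In the sugar sensing list sug, a sugar-responsive transcription factor, was higher with the label on both diets, at 2.07 ± 0.26 and 2.11 ± 0.26, and daw, an activin-like ligand, lower, at -1.75 ± 0.19 and -0.97 ± 0.19. Yp3, a yolk protein gene, was the 1 of 4 sex markers that passed, at -3.21 ± 0.48 and -2.74 ± 0.48 (1 lower adjusted over the list alone on each diet; camera adjusted p = 0.25 and 0.279, limma with Benjamini-Hochberg).

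Detoxification genes changed both ways with the label on 0.5 M sucrose, 6 higher and 6 lower of 27 (7 and 6 adjusted over the list alone; camera adjusted p = 0.809, limma with Benjamini-Hochberg), with GstE9 at 2.43 ± 0.19 and GstD10 at -2.72 ± 0.51. With diet in controls 3 rose and 1 fell (4 and 1 adjusted over the list alone), camera adjusted p = 0.0149 (limma, Benjamini-Hochberg) and adjusted p = 0.682 with an estimated correlation, and 0.206 without control 0.5 M replicate 1. In the ribosome biogenesis list 3 of 19 rose with the label on 0.5 M (3 adjusted over the list alone, camera adjusted p = 0.959, limma with Benjamini-Hochberg). Over all genes 1100 of 10047 rose in that comparison. In the midgut list 3 of 12 fell with the label on 0.5 M (3 adjusted over the list alone; camera adjusted p = 0.308, limma with Benjamini-Hochberg), deltaTry at -1.46 ± 0.29, Npc2f at -1.12 ± 0.26 and Jon65Aiv at -1.05 ± 0.26, and Jon65Aiv had adjusted p = 0.0559 without EcRi 0.5 M replicate 3. Of 4 further tissue lists on 0.5 M, 1 of 11 nervous system genes, cpx, 1 of 5 gonad and germline genes, Mst87F, 1 of 5 Malpighian tubule genes, ZnT35C, and 0 of 6 genes of cuticle and trachea passed in limma, the last with 0 in voom and 0 at an unadjusted p under 0.05. Adjusted over the list alone these counts were also 1, 1, 1 and 0. cpx and Mst87F were higher, at 1.14 ± 0.23 and 2.43 ± 0.38, and ZnT35C lower, at -1.20 ± 0.18 (camera adjusted p from 0.191 to 0.444 for the 4 lists, limma with Benjamini-Hochberg).

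The level of EcR did not fall detectably in the libraries labelled EcR RNAi. Single mislabelled libraries are argued against, since on genes with a fold of at least 4 on the other diet every library lay within 0.088 of its own genotype's mean, on a scale where the other genotype lies at 1. A swap of whole groups was not tested by itself, though values that run with the labels were w, higher in the libraries labelled EcR RNAi, and the ecdysone response genes E23 at -2.05 and -1.98, Eip78C at -1.79 and -1.69 and Eip75B at -1.48 and -1.38 on 0.15 M and 0.5 M, in a list with 10 lower and 1 higher of 24 on 0.15 M and 8 lower and 5 higher on 0.5 M (adjusted p = 0.538 and 0.691 with an estimated correlation). Reads from the hairpin may add to the signal of EcR, and this cannot be told apart from a weak knockdown here, since the 95% interval on 0.15 M reached down to -0.6485 and values per exon were not used here.

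Of the 8 salivary gland genes 7 were lower in the libraries labelled EcR RNAi on 0.15 M and 4 on 0.5 M (adjusted p = 0.427 and 0.691 with an estimated correlation, limma camera with Benjamini-Hochberg), with ng3 at 0.25 ± 0.35 and 0.93 ± 0.35 not passing, and less carried-over gland tissue is a candidate explanation for the falls. As the whole cause it would leave the ratios between these genes unchanged, provided that each had signal from the gland alone. The ratio to Sgs3 differed between genotypes for 4 of 7 other glue genes on 0.15 M and 3 on 0.5 M. Examples on 0.15 M were 4.264 ± 0.537 (log2, SE) for ng3 and -1.576 ± 0.537 for Eig71Ee (limma, Benjamini-Hochberg adjusted p = 6.71e-10 and 0.0112). Signal of these genes from other tissue was not tested and would shift the ratios too, so they do not settle this explanation. All 7 ratios share Sgs3 and 1 SE, 0.537, so they are not separate tests and their p-values may be too small. ng3 also rose with diet in controls. Apart from ng3, the ratio of Sgs5 rose by 1.832 on 0.15 M while that of Eig71Ee fell. On 0.15 M Sgs3 lay at 1961 ± 703 in controls and 116 ± 17.8 with the label (SD, n = 3 each), and no other list holds any of the 8 salivary gland genes. Less gland tissue alone stays open. A difference in tissue share together with a difference in the glands, or in the timing of the larvae, stays open and untested.

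In each of the 4 comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. The real split was the 1 with the most genes, with 1125, 1915, 173 and 2451 called for genotype on 0.15 M and 0.5 M and for diet in controls and in libraries labelled EcR RNAi, against highest other counts of 0, 0, 2 and 0. Every other split mixes libraries of both groups, so a real difference widens its spread and lowers its count. The gap in gene counts thus does not exclude chance. For lists called by camera the real counts were 8, 7, 12 and 14 and the highest others 14, 14, 14 and 16, with 4, 5, 4 and 3 of the 10 splits giving as many. For the overlaps the real pair of splits, 1 of 100, shared 682 genes for genotype and 113 for diet and the highest other 0. Since the other splits called at most 2 genes they could not share as many, so this comparison decides nothing about chance in the overlaps.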
